A study of Mus musculus with 5 samples.

How the data were processed

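Snap-frozen atria were sequenced by the submitters as stranded polyA libraries. FastQC, MultiQC, Trim Galore, STAR, RSEM, SAMtools, limma and edgeR, and the build GRCm39, are named per the submitters' processing notes, without versions. RSEM gene and transcript tables of 5 libraries hold expected counts, per the file headers, which the authors estimated and did not normalize. The same deposited tables hold TPM values, scaled by the authors to transcript length and library total, and the transcript tables give the authors' isoform percent of each gene. The authors' deposited table of their own comparison holds log2 fold changes, moderated scores (t) and p-values. From its values it was a limma test against a minimum fold of 1.2, a step inferred here and not stated in the sources used here.

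Groups came from the sample titles: 3 het and 2 WT libraries. Sex is not in the labels used here. Expected counts were rounded to whole numbers. Of 57186 genes, 16412 passed edgeR's default expression filter. Libraries were scaled by TMM and tested with edgeR's quasi-likelihood test with robust dispersions, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 0.18. SEs are the absolute log2 fold change divided by the square root of F. CPM are given as mean ± SD over libraries. With 3 against 2 libraries there are 10 splits, so the smallest two-sided exact p is 0.2, and single comparisons cannot pass 0.05 by an exact test. Total expected counts of 17784601 to 28353091 per library set the precision.

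The test, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Named were Mrc2, the 10 genes per direction with the smallest p among those called, with a mean of at least 1 CPM, no overlap between groups and a symbol of a characterised gene, up to 4 called members of each list (or up to 2 of the highest level where none was called), and the 5 genes per direction with the smallest p in the authors' deposited table. Some genes that this rule names are not reported here. Of 46 lists, 44 had at least 3 tested members and were tested with camera at a preset correlation of 0.01. Alternatives were camera with an estimated correlation, fry, and camera on limma-voom values. For genes, alternatives were DESeq2, limma-voom with and without quality weights, other scalings and filters, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a covariate of Y-linked expression, and each library left out. Length and GC trends per library, fitted with mgcv and entered as edgeR offsets, a length trend alone, and a mean of at least 5 CPM were added after the data were seen.

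The reference annotation used here is of another build than the submitters' GRCm39, so no coordinates are given. It served for symbols, chromosomes, gene order and GC content, with GC known for 97.9% of tested genes. A comparison of genes within set distances of Mrc2 was planned and not run, and gene order took its place. Reads shared between near-identical genes, such as ribosomal protein genes and their pseudogenes or Hbb and Hba genes, are split by RSEM's model, so those levels are uncertain.

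The code was tested on simulated data for het against WT with 200 changed genes. On 16013 genes without a trend, 68% of genes with a log2 fold change of 1 and 91% of those with 2 were recovered, and 16 of 175 calls (9.1%) were false, above the 5% aimed at. With a simulated length trend on 15942 genes, 452 of 622 calls were false, and 21 of 187 with length offsets. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3.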

Results

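Atrial tissue of mice heterozygous for the E990G change in MRC2 (het) and of wild-type mice (WT) was profiled by stranded polyA RNA sequencing. MRC2 is an endocytic collagen receptor of mesenchymal cells. Libraries of 3 het animals (replicates 5, 6 and 7) and 2 WT animals (replicates 7 and 8) of batch 2 were analysed here, out of 7 het and 8 WT animals aged 4 to 10 months that the series describes. Total expected counts per library ran from 17784601 (WT 8) to 28353091 (het 7). The WT 8 library, the shallowest, therefore gives the least precise counts of low-level genes. Mitochondrially encoded genes took 13% (het 7) to 17.7% (het 5) of the counts. The first principal component of log2 CPM values held 45.1% of the variance and separated the het from the WT libraries. The labels used here do not give sex: WT 7 had 938 expected counts of the Y-linked gene Ddx3y and 22 of Xist, while the other 4 libraries had at most 3 of Ddx3y and 6117 or more of Xist.

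The variant allele was compared first for the level of its own gene. Mrc2 (ENSMUSG00000020695) stood at 38.6 ± 7.9 CPM in het (SD, n = 3) and 38.9 ± 6.7 CPM in WT (SD, n = 2) atria. Its log2 fold change was -0.01 (SE 0.18, edgeR quasi-likelihood adjusted p = 0.973). This difference was smaller than the spread between replicates, and its sign turned with library size alone as scaling (0.029) and with het 5, het 6 or WT 7 left out (0.002, 0.12 and 0.18). One transcript, ENSMUST00000100335, held 99.1% ± 0.41 of the Mrc2 expected counts in het and 99.3% ± 0.55 in WT (exact two-sided permutation p = 0.80). An amino acid exchange is not visible in gene counts, so Mrc2 counts do not check the genotype labels.

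Across the transcriptome, the question was which genes differ in atria that carry the variant. Hipk2, a nuclear kinase, was higher in het atria (86.7 ± 12.3 CPM, SD, n = 3, against 33.8 ± 9.1 CPM, SD, n = 2). It rose by 1.36 on the log2 scale (SE 0.19) and Ppara, the fatty acid sensing nuclear receptor, by 1.31 (SE 0.18). The chemokine gene Cxcl1 (1.66, SE 0.24) and the transcription factor gene Zbtb16 (1.5, SE 0.20) rose as well. Tagln, a smooth muscle actin-binding protein gene, fell by 0.93 (SE 0.14), and the protocadherin gene Pcdhgc4 fell by 1.08 (SE 0.14). Each of these genes had an adjusted p of 0.0229 in the edgeR quasi-likelihood test. With length and GC trends removed none of them was called. The higher folds then ran from 1.17 (Hipk2) to 1.75 (Cxcl1), with Tagln at -0.77 and Pcdhgc4 at -0.996.

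Other genes that the naming rule placed first were Pdpr, Tmtc3, Cep350, Ep300 and Pcm1 on the higher side. Their log2 fold changes ran from 0.81 (Pcm1) to 1.21 (Pdpr), and from 0.35 (Pcm1) to 1.02 (Pdpr) with length and GC trends removed. On the lower side stood Hspb2, Arl4d, Prdx5, Timm13, Hint2, Myl1, Mrpl53 and Lsm4, from -0.74 (Mrpl53) to -1.002 (Arl4d). Prdx5, a mitochondrial peroxiredoxin gene, had 195.0 ± 5.7 CPM in het and 331.8 ± 2.5 in WT. Timm13 and Mrpl53 also encode mitochondrial proteins. All 13 had an adjusted p of 0.0229 in the edgeR fit. With length and GC trends removed none of the 13 was called, and those on the lower side ran from -0.28 (Lsm4) to -0.72 (Arl4d).

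**Figure D1:**
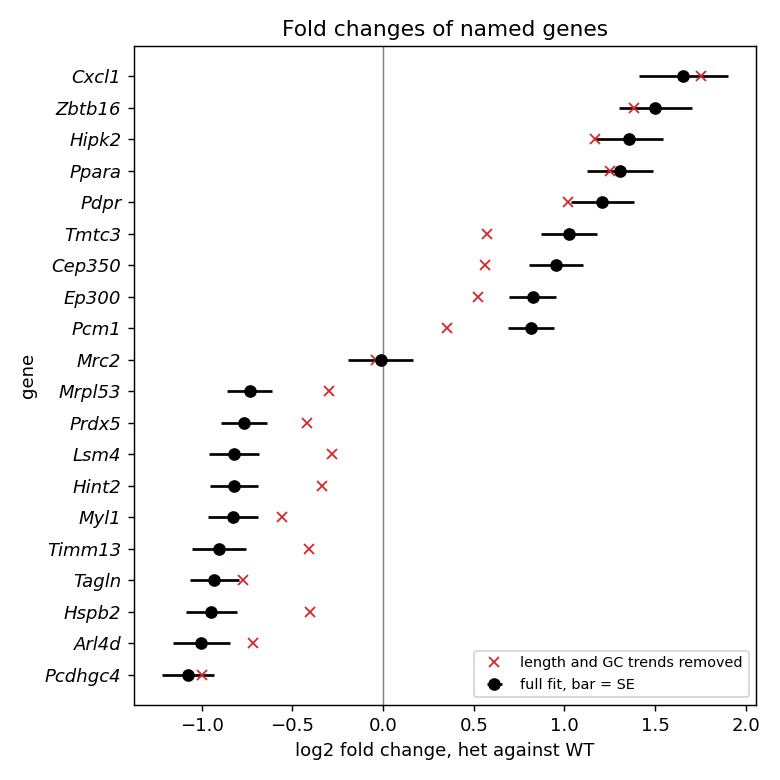
Log2 fold change (x axis) of Mrc2 and of named genes (y axis), het against WT, with the SE as bars (3 het and 2 WT libraries); crosses give the values after length and GC trends were removed. Mrc2 lies at -0.01 with an SE of 0.18, Cxcl1 is the highest at 1.66 and Pcdhgc4 the lowest at -1.08.

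In total 490 genes were higher and 436 lower in het among 16412 tested (edgeR, adjusted p under 0.05), and 4061 had an unadjusted p under 0.05. At least 2-fold changes numbered 38 higher and 129 lower. Of the lower genes, 104 had a mean under 1 CPM, against 2 of the higher ones. Olfactory receptor genes, silent in most tissues, summed to 96.9 (WT 7) and 120.0 (WT 8) CPM and to between 29.8 and 39.8 CPM in the het libraries. In 42.3% of tested genes the het and WT libraries did not overlap, where chance gives 20% for 3 against 2. The split depended on scaling: library size alone gave 795 higher and 391 lower, and upper-quartile scaling gave 327 and 568. Without het 5, het 6 or het 7 the calls fell to 0 and 1, to 5 and 6, and to 0 and 0 higher and lower genes. All 926 genes were picked with the 5 libraries and had no overlap between groups, so their folds could change little with 1 het library fewer. Their median absolute log2 fold change stayed at 0.66, 0.62 and 0.67 in these fits (0.64 with all libraries), and 3139 to 3595 genes had an unadjusted p under 0.05. Without WT 7 they were 260 and 134, and without WT 8 they were 588 and 290. Those 2 fits left 1 WT library, which was assumed to vary like the het libraries. The fit with sample quality weights called 0 genes in limma-voom (3632 at an unadjusted p under 0.05), where limma-voom without weights called 237 higher and 222 lower.

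Fold changes followed transcript length. In the shortest decile of tested genes the median log2 fold change was -0.38, with 4 higher and 154 lower calls. In the longest decile the median was 0.33, with 261 higher and 28 lower calls. With per-library trends on length and GC content removed, an alternative chosen after seeing the data, edgeR called 0 genes. The smallest adjusted p was then 0.0504, just past the threshold, and 130 genes lay under an adjusted p of 0.1 (1835 at an unadjusted p under 0.05). The median absolute log2 fold change of the 926 called genes went from 0.64 to 0.30, and 99.7% of them kept their sign.

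**Figure D2:**
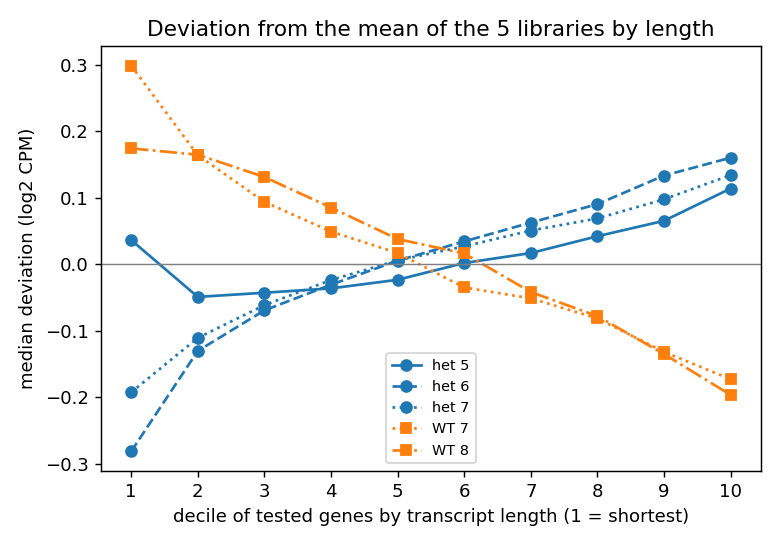
Median deviation of each library from the mean of the 5 libraries (y axis, log2 CPM) in deciles of the tested genes by length (x axis, 1 = shortest). The het libraries (circles) lie below the WT libraries (squares) among short genes and above them among long genes, which corresponds to median log2 fold changes of -0.38 and 0.33.

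Genes of oxidative phosphorylation were lower in het as a set. Of 65 tested, 0 were higher and 15 lower, and 44 were lower when adjusted over the list alone. The median log2 fold change was -0.52, where the same genes had a median of 0.049 in the authors' deposited table. Ndufs7, a complex I subunit gene, fell by 0.75 (SE 0.13), Cox4i1, of cytochrome c oxidase, by 0.74 (SE 0.14), and Uqcrq, of complex III, by 0.82 (SE 0.17). In edgeR's fit the list passed camera with a preset correlation (adjusted p = 3.1e-20), but not with an estimated one (adjusted p = 0.916 with an estimated correlation). With an estimated correlation the smallest adjusted p of any list was 0.888. With 5 libraries that camera test has little power, so failing it says little about a list. Oxidative phosphorylation genes are short, with a median length of 718 bases. Their median moved to -0.21 once length and GC trends were removed. The list then still passed camera with a preset correlation (adjusted p = 2.0e-08). The 13 mitochondrially encoded genes had 0 calls and a median of 0.003, with 1 higher when adjusted over the list alone; in the authors' deposited table their median was 0.88.

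Glycolysis and sarcomere genes were also lower by the preset-correlation camera test (adjusted p = 0.0025 and 0.0041), but not with an estimated one (adjusted p = 0.916 for both with an estimated correlation). The glycolysis call was also lost without het 5 (adjusted p = 0.064) or WT 8 (0.162), and the sarcomere call without WT 8 (0.086). Of 26 glycolysis and glucose uptake genes 0 were higher and 4 lower (9 lower when adjusted over the list alone), among them Pgam2 (-0.79), Aldoa (-0.61) and Gapdh (-0.55). Of 26 sarcomere genes Nebl, a nebulin-like protein gene, was higher (0.77) and 3 were lower (1 and 8 when adjusted over the list alone), among them Tpm1 (-0.69) and Tnni3 (-0.60). Skeletal muscle markers passed camera (adjusted p = 0.0017, and adjusted p = 0.888 with an estimated correlation) and had 2 lower of 8 tested (5 when adjusted over the list alone), Myl1 (-0.83) and Ckm (-0.70). Cytosolic ribosomal protein genes had 0 calls of 53 and a median of -0.36 (camera adjusted p = 9.3e-07, and adjusted p = 0.967 with an estimated correlation). After removal of length and GC trends the ribosomal median was 0.03, and the sarcomere median went from -0.31 to -0.14. The glycolysis median went from -0.28 to -0.22 and the skeletal muscle median from -0.76 to -0.54. Sarcomere, glycolysis and skeletal muscle lists then still passed camera with a preset correlation (adjusted p = 0.024, 0.0064 and 0.012). Folds such as those of Pgam2 (-0.33), Gapdh (-0.27) and Tnni3 (-0.16) shrank. In the authors' deposited table the medians of the sarcomere, skeletal muscle and ribosomal lists were above 0 (0.11, 0.012 and 0.22), and that of the glycolysis list was -0.087.

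Markers of blood and immune cells were higher in het by the preset-correlation camera test. The erythroid list had a median of 1.37, with 1 of 9 genes higher and an adjusted p of 9.9e-06 (adjusted p = 0.916 with an estimated correlation). Hbb-bs, a haemoglobin gene, stood at 1611 ± 756 CPM in het and 614.3 ± 479 in WT, with each het library above both WT libraries, but did not pass the test (adjusted p = 0.408). Of 25 macrophage and monocyte markers 2 were higher, Adgre1 (1.14, SE 0.22) and Cd163 (1.03, SE 0.22). That list had an adjusted p of 0.0006 (adjusted p = 0.919 with an estimated correlation). The neutrophil and mast cell list had 0 of 7 genes called, and 3 higher when adjusted over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.888 with an estimated correlation). That call was lost without het 5 (adjusted p = 0.064) or WT 8 (0.086), and with a mean of at least 1 CPM (0.073). Lymphocyte markers had 1 higher of 20, Igkc (2.01; 3 when adjusted over the list alone), and inflammatory cytokines 1 of 31, Cxcl1; neither list passed the test (adjusted p = 0.102 and 0.078). Both passed as higher without het 7 (5.7e-04 and 4.3e-04), with every gene with a count (0.0022 and 0.0013) and with length and GC trends removed (0.012 and 0.011). In the authors' deposited table the medians were 0.64 for the erythroid, 0.14 for the macrophage, 0.005 for the neutrophil and mast cell, -0.16 for the lymphocyte and 0.083 for the inflammatory list.

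Matrix genes were of interest because the receptor binds collagen and the series names fibroblast dysfunction. Of 14 fibrillar and beaded collagens Col14a1 was higher (0.70, SE 0.13) and 0 were lower (3 higher when adjusted over the list alone). Collagen processing and crosslinking had 0 calls of 26 and basement membrane 0 of 20. In the collagen uptake and degradation list 1 of 30 was higher, the collagen-binding receptor kinase gene Ddr2 (0.65), and 0 were lower (0 and 0 when adjusted over the list alone). Of 46 matricellular and proteoglycan genes 2 were higher and 1 lower, namely Lum (0.50), Thbs2 (0.59) and Ccn1 (-0.49), and 5 and 3 when adjusted over the list alone. TGF-beta signalling and myofibroblast genes had 2 higher, Tgfbr1 (0.75) and Smurf2 (0.50), and 2 lower, Tagln and Tpm1, of 45 (3 and 3 when adjusted over the list alone). With length and GC trends removed Col14a1 stood at 0.54, while Ddr2 (0.29), Lum (0.29), Thbs2 (0.28), Tgfbr1 (0.33) and Smurf2 (0.19) shrank more, and none was called. Fibroblast markers had 2 higher of 27, Lum and Ddr2 (3 higher and 1 lower when adjusted over the list alone). The mixed fry test counts changes in either direction and does not set a list against the other genes. With 4061 of 16412 genes at an unadjusted p under 0.05 in edgeR, 18 of the 44 lists passed it. TGF-beta and myofibroblast genes (adjusted p = 0.012), collagen uptake (0.022), matricellular genes (0.039) and fibroblast markers (0.049) passed it. With directional fry 0 lists passed. None of the matrix lists passed camera, with adjusted p from 0.306 to 0.922. Without WT 7, which leaves 1 WT library, fibroblast markers (adjusted p = 3.9e-04), basement membrane (0.0072) and fibrillar and beaded collagens (0.021) passed as higher. With every gene with a count, collagen uptake (0.0028) and fibroblast markers (0.029) did.

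Atrial and electrical genes were compared because the series concerns atrial fibrillation. Nppa, the atrial natriuretic peptide gene, was lower in het (19544 ± 1540 against 30492 ± 4751 CPM, log2 fold change -0.64, SE 0.16). Myl4, the atrial light chain gene, fell by 0.68 (SE 0.15), and Adm by 0.61 (SE 0.15). Thus 3 of 19 atrial genes were lower and 0 higher (4 lower when adjusted over the list alone). Of 53 ion channel and gap junction genes 5 were higher and 0 lower, among them Kcnj2 (0.70), Abcc9 (0.70), Cacna2d1 (0.63) and Kcnd3 (0.53), and 9 higher and 1 lower when adjusted over the list alone. Ryr2, the sarcoplasmic calcium release channel gene, rose by 0.69 (SE 0.14), within a calcium handling list of 2 higher and 2 lower among 37 (3 and 3 when adjusted over the list alone). Of 28 atrial fibrillation and conduction genes Tbx20 was higher (0.51). With length and GC trends removed these folds shrank and none of the genes was called: Nppa went to -0.23 (SE 0.16, adjusted p = 0.635), Myl4 to -0.32, Adm to -0.39, Kcnj2 to 0.25, Abcc9 to 0.35, Cacna2d1 to 0.20, Kcnd3 to 0.31, Ryr2 to 0.35 and Tbx20 to 0.095. The median of the ion channel list went from 0.073 to 0.004, and that of the fibrillation and conduction list from 0.15 to -1.1e-04. The mixed fry test does not set a list against the other genes. By it ion channels (adjusted p = 0.0030), calcium handling (0.0030), fibrillation and conduction genes (0.020) and atrial genes (0.028) passed. None of these lists passed camera, with adjusted p from 0.071 to 0.951. Atrial genes passed as lower with a mean of at least 1 CPM (adjusted p = 0.031) and without het 7 (0.039). Ion channels passed as higher without WT 7 (0.023) and, like the fibrillation and conduction list (0.022), with every gene with a count (0.0021).

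The remaining lists held few calls. Cardiac stress genes had 2 lower of 19, ventricular genes 1 lower of 13, and smooth muscle and pericyte markers 1 higher and 1 lower of 15. Fatty acid oxidation had 2 higher (Ppara and Ppargc1a) and 2 lower of 36. Immediate early genes had 1 higher (Fosb, 1.14) and 3 lower of 26, among them Ier5 (-0.76) and Nr4a1 (-0.63). The unfolded protein response had 1 higher of 25, lymphatic endothelium 1 higher of 7, complement 1 higher of 19, and glucocorticoid response 1 higher of 16. Hypoxia genes had 1 higher and 1 lower of 18, endothelial markers 1 lower of 21, heat shock genes 1 lower of 18, and brown adipocyte markers 1 higher of 9 (Ppara, which 2 lists hold). Adjusted over the list alone, cardiac stress genes had 1 higher and 3 lower, ventricular genes 2 lower, and the unfolded protein response 3 higher. There were 0 calls among interferon, lysosome, white adipocyte, Schwann cell, lung epithelial, epicardial, circadian, cell cycle and cholesterol lists. None of these lists passed camera, and thymus markers and sex-linked genes had 1 tested member each, too few for the test. Mixed fry again set no list against the other genes. Passing it were lysosome (adjusted p = 0.0076), smooth muscle and pericyte (0.012), hypoxia (0.022), endothelial (0.023) and unfolded protein response genes (0.025). Some of the remaining lists also passed camera under other settings. Interferon genes passed as higher without het 5 (adjusted p = 3.3e-05), with length and GC trends removed (0.012) and with every gene with a count (0.0018). Smooth muscle and pericyte markers passed as lower without het 7 (0.049) and with length and GC trends removed (0.025). Lymphatic endothelium passed as higher without het 7 (0.049), and the unfolded protein response without WT 8 (0.0073), and both did with every gene with a count (0.0038 and 0.0022). Cardiac stress genes passed as lower without het 5 (0.025) or WT 7, and ventricular genes without het 6 (0.0098) or WT 7. The fit without WT 7 holds 1 WT library. White adipocyte (2.2e-09) and cholesterol genes (0.0048) passed as lower without het 7. Fasn and Scd1, which both of these lists hold, had 535.1 and 679.0 CPM in het 7. In the other libraries they had 34.5 to 124.3 and 53.4 to 138.8 CPM. Glucocorticoid genes passed as lower without het 6 (0.043), and sex-linked genes with every gene with a count (0.041). Heat shock genes without WT 7 and sex-linked genes without WT 8 also passed as lower, in fits with 1 WT library. The sex-linked list holds Xist, Tsix and Y-linked genes. Y-linked Ddx3y had 938 expected counts in WT 7 and 0 to 3 in the other libraries, so the sex-linked calls rest on WT 7.

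The authors' deposited table, a fit over the series' animals, gives per-gene fold changes of het against WT. Of the 14927 genes of the authors' deposited table, 0 had an adjusted p under 0.05 (smallest 0.277), and 287 higher and 2 lower genes had an unadjusted p under 0.01. In the authors' deposited table Hipk2 had the smallest unadjusted p of the genes the rule named (log2 fold change 1.59, adjusted p = 0.312). It was followed there by Acvr2b (1.59), Kcna1 (1.78), Col27a1 (1.25) and Sox9 (1.34) on the higher side. Sdr39u1 (-0.77), Cntf (-1.56), Srp54b (-1.01), Dhrs11 (-0.83) and Ddit4 (-1.17) came first on the lower side of the authors' deposited table. Of these 10 genes only Hipk2 was called in the 5 libraries. Of the 926 called genes, 819 were in the authors' deposited table, and 556 of these (67.9%) had the same sign there. Tagln was among those with the opposite sign in the authors' deposited table (0.36).

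Of the 100 genes with the smallest p in the authors' deposited table, 74 were tested in the 5 libraries and 49 had the same sign. That is 66.2% (95% exact binomial interval 54.3 to 76.8). The interval treats genes of the same libraries as independent, so it does not measure the spread between animals. All 100 were higher in het in the authors' deposited table, so this is the share with a positive fold in the 5 libraries. Other splits of the same libraries into 3 and 2 gave 31.1% to 68.9%. Across 14700 shared genes, which are not independent replicates, the fold changes correlated at a Pearson r of 0.16 and a Spearman rho of 0.27. The series text makes these 5 animals part of the authors' fit, so the comparison is not independent.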

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

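The removal of length and GC trends, of the length trend alone, and the filter at a mean of 5 CPM were chosen after seeing the data; the other alternatives were fixed before. Against 490 genes higher and 436 lower in het, DESeq2 gave 869 higher, limma-voom 237 and 222, and limma-voom with quality weights 0 and 0 (smallest adjusted p 0.0544). Library size alone gave 795 higher, every gene with a count 1304 and 907, the fit without robust dispersion 78 and 57, and the Y-linked covariate 219 and 125. Limma-trend gave 0 and 1 on log2(TPM + 1), and 2 and 3 on log2(TPM + 0.1). Removing the length trend left 6 and 10 calls, all 16 of them also called before, and removing length and GC trends 0 and 0. With 1 library left out the counts ran from 0 to 588 higher and from 0 to 290 lower, and leaving out any het library left at most 9 of the 926 genes called. DESeq2 and the use of every gene with a count shifted the median log2 fold change of all genes to -0.18 and -0.14. The length and GC trends were removed by construction, and the cause of the other differences was not tested.

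Mrc2 was not called under any alternative (unadjusted p from 0.179 to 0.9995), but its sign turned with DESeq2 (1.3e-04), library size alone (0.029), every gene with a count (0.038), TPM values (0.16 with a pseudocount of 1, 0.18 with 0.1) and the Y-linked covariate (0.17). With 1 library left out it ran from -0.18 to 0.18. The difference in the share of its main transcript moved from -0.20 to -3.85 percentage points when TPM replaced counts.

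Of the gene lists, 8 passed camera, 0 with an estimated correlation, 0 with directional fry, 18 with mixed fry, 18 with every gene with a count, and 8 to 16 with 1 library left out. Of the 8, glycolysis and neutrophil and mast cell genes (the latter also with a mean of at least 1 CPM) lost their call without het 5 (adjusted p = 0.064 each) or WT 8 (0.162 and 0.086), and sarcomere genes without WT 8 (0.086). With length and GC trends removed 11 lists passed, among them all of the 8 but the ribosomal one. For genes changed in the authors' deposited table, the count was 289 at an unadjusted p under 0.01 and 0 at either adjusted threshold. Sign agreement rose from 66.2% to 79.6% with a mean of at least 1 CPM, and was 56.8% with length and GC trends removed.

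Of 82 other genes followed across the alternatives, 69 were called in the full fit. All 69 lost their call with length and GC trends removed, and all 69 lost it without het 5. Among the 82, signs turned with length and GC trends removed for Sdr39u1 (0.053), Dhrs11 (0.036), Srp54b (-0.16), Rps2 (0.054) and Rplp0 (0.087), none of them called. Srp54b also turned with the Y-linked covariate (-0.15) and ran from -0.16 to 0.52 with 1 library left out. Acvr2b turned with TPM values (-0.41 and -0.63) and ran from -0.24 to 0.82, and Kit from -0.13 to 0.36. No paired analysis was possible because the groups share only replicate number 7. Genes within 5 or 20 Mb of Mrc2 were not run.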

Other observations

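The tests of the length trend, of silent gene families and of other splits were chosen after the result was seen, as was the reading of the fit without WT 7, itself planned, as a test of sex; the test of genes next to Mrc2 was set before its result was seen. Some cell type markers stood apart in single libraries. Ucp1, the thermogenic gene of brown fat, had 34.6 CPM in het 7, 0 counts in het 5 and het 6, and 0.45 and 0.90 CPM in WT 7 and WT 8. Cidea, another brown fat gene, had 28.0 CPM in het 7 and 8.8 to 12.4 CPM in the other libraries. Myl2, the ventricular light chain gene, ran from 1.0 CPM in het 7 to 79.1 CPM in het 6, with 30.4 and 34.2 CPM in WT 7 and WT 8. Among neutrophil and mast cell markers, the mast cell genes Cpa3 and Cma1 had log2 fold changes of 2.38 (SE 0.83) and 1.48 (SE 0.48), and S100a9, a neutrophil gene, 3.15 (SE 1.02). None of these 3 was called over all genes (edgeR adjusted p = 0.098, 0.080 and 0.080), and they were chosen after their values were seen.

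The authors' deposited table leaned to one side. Of its 100 genes with the smallest p, 100 were higher in het, and 66 of these had symbols of predicted genes or clones, against 10.4% of the table.

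Longer genes were higher and shorter genes lower in het. GC content in place of length is argued against, since the partial Spearman correlation across genes of log2 fold change with length given GC was 0.41, beside -0.31 with GC given length. An effect of the genotype of this size in every animal was not seen in the authors' deposited table. There the longest decile of genes exceeded the shortest by 0.078, against 0.74 in the 5 libraries over the same 14700 genes. The 95% bootstrap interval of the former (0.051 to 0.105) resampled genes and not animals, so it leaves out the spread between animals. How the authors' fit treats length was not tested. A library-wide trend on length and GC is a candidate explanation for most of the calls: with it removed, the median absolute log2 fold change of the called genes was 0.47 of its former value (0.64 to 0.30) while the median SE went from 0.14 to 0.13, so that calls ended because folds shrank. The smallest adjusted p of 0.0504 leaves open that genes such as Cxcl1 (1.66 before and 1.75 after) and Hipk2 (1.36 and 1.17) differ beyond the trend, and since both WT libraries lie on one side, RNA quality and genotype remain open for these 5 libraries.

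Genes of families silent in most tissues had more reads in the WT libraries. Of 6 families 4 were more than 2-fold higher in WT with no overlap of libraries, but the reads of olfactory and vomeronasal receptors had been seen when that bound was set, and the fourth, beta-defensins, takes most of its reads from Defb42 (1.12 of the 1.36 CPM in WT). Without Defb42 the beta-defensins still differed 5.48-fold with no overlap of libraries (0.23 CPM in WT and 0.042 in het). A genome-wide background such as genomic DNA cannot be told apart from other sources: per kb of transcript, the WT excess of the bitter taste receptor, keratin-associated protein and beta-defensin genes was 41.6% of that of the receptor families, with an upper 95% counting bound of 81.7%, and only 83 WT reads lie in them.

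Sex of WT 7 cannot be told apart from other sources of the calls. Among the 4 libraries with Xist reads, without WT 7, 394 genes were called, 222 of them also among the 926. The median absolute log2 fold change of the 926 genes stayed at 0.61 (0.64 with all libraries), and was 0.62 with the Y-linked covariate, so that the lost calls do not speak for sex as the source. Still, these genes were picked with WT 7 included, and that fit holds 1 WT library, whose spread is taken from the het libraries. On the X or Y chromosome 36 of 506 tested genes were called (odds ratio 1.28, 95% interval 0.88 to 1.81). For the real grouping 926 genes were called and the highest of the other splits gave 4; 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

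One hypothesis was that sequence of another strain flanks the altered Mrc2 allele and could change its neighbours. Of the 100 tested genes nearest to Mrc2 in gene order, 5 were called (5.0%, against 5.6% of the others), with a one-sided Fisher's exact p of 0.67 and an odds ratio of 0.88 (upper 95% bound 2.13). Of 95 of these neighbours in the authors' deposited table, 3, namely Tanc2, Bptf and Helz, had an unadjusted p under 0.01, against 1.9% of its genes. Among tested genes Tanc2 lies next to Mrc2 on 1 side. Tlk2, next to Mrc2 on the other side, had an unadjusted p of 0.97 in the authors' limma test. The data neither show such an effect nor exclude one of up to that bound. The called neighbours were Myl4, Psmc5, Smurf2, Bptf and Abca8b.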
